A study of Mus musculus with 6 samples.

How the data were processed

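The experiment covers 6 samples of the mouse cell line 32D, 3 that expressed miR-9 and miR-9* and 3 with the empty vector. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were kept in medium with 10% fetal calf serum and 10 ng/ml interleukin-3, RNA was extracted with Trizol, and biotinylated cRNA was made from 6 ug of total RNA by the Affymetrix protocol, with 1 label and therefore 1 colour per array. The scanner and its settings are not given in the sources used here.

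The deposited values are MAS5 signal intensities, per the submitters' processing notes, which name MAS5 without a version. MAS5 combines the probe pairs of a probe set into 1 signal. The deposited intensity columns are on a linear scale: all values are above 0, the mean without the lowest and highest 2% is 100 on each array, and genes were not centred. Median signals ran from 12.0 to 15.1. Detection calls were not used here, so dim probe sets were recognised by their signal alone. Of 45101 probe sets, 64 are Affymetrix controls. Names came from a 2016 platform annotation: 34958 probe sets carry 1 gene symbol, 932 several and 9160 none in that table. Of those with 1 symbol, 34754 were matched by Entrez ID to a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used for names and for grouping genes by chromosome. No gene was named from a probe set with several symbols. The 18194 genes with a probe set of their own were each represented by the probe set with the highest mean.

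Signals were transformed to log2(signal + 16) without further normalization. Probe sets with a mean log2 value below the median of all probe sets, 4.86 or a signal of 12.9, were left out, which left 10208 genes. The arms were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. This design, without a block and with 4 residual degrees of freedom, was fixed before the data were examined, as were the gene lists, the naming rule and most of the alternatives. The fit with the replicate number as a block was fixed as an alternative. Whether the numbers pair the samples was checked before its calls were compared. Across genes, deviations of the same-numbered arrays from their arm means correlated at 0.491, 0.616 and 0.680, all above the limit of 0.1, and the largest correlation between arrays of different number was -0.04. Deviations within an arm cancel out, so high same-number correlations push the others down, and the latter are not separate evidence. Few ways exist to match so few arrays, so a match by chance is not excluded. The first principal component, with 45.7% of the variance, separated the replicate numbers. The pairing is therefore read from the data, since the labels give only the numbers. Blocked values stand beside each result whose call they change. Genes are not independent replicates, so these correlations carry no p-value.

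Gene lists were tested with limma's camera with its preset correlation of 0.01, adjusted over all 30 lists, with an estimated correlation and with fry as alternatives. The lists cover reported miR-9 targets, primary granule and early neutrophil genes, secondary and tertiary granule and late neutrophil genes, haematopoietic transcription factors, stem and progenitor markers, G1/S and DNA replication genes, G2/M genes, G1 cyclins and CDK inhibitors, the interleukin-3 and STAT5 response, apoptosis regulators, FOXO and p53 target genes, and interferon, NF-kB, immediate early and unfolded protein responses. They also cover cholesterol genes, glycolysis and hypoxia, cytosolic ribosomal proteins, oxidative phosphorylation, neuronal genes under REST, microRNA machinery, BAF and CoREST chromatin regulators, and adhesion and surface receptors. Marker lists cover monocytes and macrophages, mast cells and basophils, eosinophils, erythroid cells, megakaryocytes and lymphoid cells. List members with no probe set of a single symbol, or below the filter, are not counted as measured.

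Named genes are the 12 largest increases and 12 largest decreases among called genes whose arms are fully separated, filled up to 6 by smallest p where fewer pass. A set of 18 genes chosen for the biology of miR-9 and of myeloid cells is always named. From each list come up to 4 called members, or the 2 with the highest mean where none is called, and every called reported target. After the pairing check the same rule was applied to the blocked fit, with all 3 pairs changing the same way in place of separated arms. Probe sets with several symbols or none were tested among all probe sets above the filter.

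The alternatives were other pseudocounts, filters, normalizations, variance models, array weights, averaging of probe sets, probe sets as units, stricter thresholds, and leaving out each array in turn. The same alternatives combined with the block, leaving out a replicate number of both arms, were added after seeing the data. On simulated data with 200 changed genes among 10208, the unblocked fit recovered 1.62%, 70.2% and 99.1% of genes changed by 0.5, 1 and 2 on the log2 scale, with 0 false calls. The blocked fit recovered 79.1%, 99.8% and 100% with 8.56% of its calls false. The simulated data held the replicate number effects of the real arrays and the residual spread of the blocked fit. The gap between the fits was therefore built in, and does not show that the block suits the real data. Noise was simulated independently for each gene. The simulation therefore does not test the preset correlation on lists whose members vary together, such as eosinophil markers (estimated correlation 0.864 without the block). With a list of 20 genes shifted by 0.3, camera called 10 of 10 with the preset correlation in both fits. With an estimated correlation it called 9 of 10 without the block and 0 of 10 with it, so the estimated correlation with the block had no power for such a shift. Comparisons of genes by seed matches in their 3' untranslated regions were planned and not run, because transcript sequences were not used here.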

Results

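Messenger RNA was measured on 6 expression arrays from 32D cells, a mouse myeloid line that needs interleukin-3 to survive and grow. In 3 samples the cells expressed miR-9 and miR-9*, the 2 strands processed from 1 microRNA precursor, and in 3 samples they carried the empty vector. Both arms grew in medium with 10% fetal calf serum and 10 ng/ml interleukin-3. The replicates are described as independent, without saying how the cultures were separated. P-values without a block therefore measure the spread between these samples. Those with the replicate number as a block measure the spread of the differences between the arms within a number. Each array holds a MAS5 signal for every probe set, scaled to a trimmed mean of 100. Median signals ran from 12 to 15.1, Spearman correlations between arrays from 0.966 to 0.987, and 0 arrays held identical values. The number of arrays limits the precision of every value below. The comparison asks which genes were higher or lower once the cells expressed both strands, with 10208 genes tested. Fold changes are differences in mean log2(signal + 16), which understate the change of dim genes. Errors on signals are SDs over n = 3 arrays.

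Cells with miR-9/9* carried more message for C1s1, a serine protease of the classical complement cascade, and for F13a1, the catalytic subunit of coagulation factor XIII. They carried less for the glycosyltransferase Galnt3, for Rap1gap, which switches off the small GTPase Rap1, and for the endoplasmic reticulum protein Reep4 and Card19. C1s1 (probe set 1424041_s_at) went from 9.62 ± 1.95 to 122 ± 38.9, a log2 fold change of 2.39 (SE 0.204, adjusted p = 0.0138). F13a1 (1448929_at) went from 183 ± 12.2 to 374 ± 35, a log2 fold change of 0.97 (adjusted p = 0.0435). Galnt3 fell from 245 ± 16.4 to 102 ± 4.71 and Rap1gap from 31.6 ± 4.46 to 3.27 ± 1.48, with log2 fold changes of -1.14 (adjusted p = 0.0314) and -1.30 (adjusted p = 0.0432). Reep4 fell from 200.1 ± 9.30 to 74.3 ± 16.1 and Card19 from 343 ± 17.0 to 144 ± 25.9, with log2 fold changes of -1.27 and -1.18 (both adjusted p = 0.0435). The call of Galnt3 was lost when its probe sets were averaged (adjusted p = 0.699).

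These 2 higher and 4 lower genes were the whole yield of the comparison of the arms without pairing, in which 470 genes had an unadjusted p under 0.05, 4.60% of those tested. After quantile normalization the split was 3 higher and 2 lower. In limma 0 genes passed without a filter on dim probe sets (892 with an unadjusted p under 0.05) and 0 with a stricter filter (373). A pseudocount of 1 left 1 higher and 1 lower, dropping the variance trend 1 and 2, and array weights gave 14 and 12. Single arrays moved these counts: limma passed 0 genes without empty vector replicate 1 (399 with an unadjusted p under 0.05), 2 higher and 0 lower without empty vector replicate 2, and 1 and 1 without empty vector replicate 3. Without miR-9/9* replicate 1 or 2 it passed 1 higher and 0 lower. Same-numbered arrays of the arms deviated together from their arm means, so the fit was repeated with the replicate number as a block. With the block, 154 genes were higher and 148 lower, all 6 genes above among them, and 1735 had an unadjusted p under 0.05. Changes were mostly small: 17 of the higher and 9 of the lower genes changed at least 2-fold on the shifted scale. Without replicate 1 of both arms the blocked counts were 86 and 76. Without a variance trend they were 21 and 17, and without a filter on dim probe sets 40 and 34. The block leaves 2 residual degrees of freedom. In data simulated with replicate number effects built in and noise independent between genes, 8.56% of its calls were false. Of the 53 genes named as passing with the block, 35 lost the call without a variance trend and 28 without a filter. Genes below that passed only with the block are marked as such.

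Of 10 erythroid markers measured, 3 rose with the block: Rhag, Gata1 and Klf1. Rhag, a membrane protein of the red cell Rh complex, had the smallest adjusted p of any gene and went from 75.3 ± 38.0 to 417 ± 77.0, a log2 fold change of 2.33 (block adjusted p = 0.000480, against 0.0741 without it). The erythroid transcription factors Gata1, from 622 ± 99.2 to 894 ± 117, and Klf1, from 54.8 ± 19.9 to 113 ± 55.1, rose by 0.52 and 0.80 on the log2 scale (block adjusted p = 0.00667 and 0.0146). Both calls were lost without a variance trend (adjusted p = 0.0801 and 0.0764), and that of Klf1 also without a filter on dim probe sets (0.0928). Without the block 0 of the markers passed, and adjusted over the list alone 3 passed with the block and 2 without it. The membrane glycoprotein Gypc, outside that list, went from 339 ± 2.21 to 575 ± 53.2 (log2 fold change 0.73, block adjusted p = 0.00205, and 0.0505 without a variance trend). As a list, erythroid markers ranked above other genes with the block (median log2 fold change 0.12, camera adjusted p = 0.0193, against 0.0824 without it). That call was lost without replicate 2 (adjusted p = 0.0742), without a filter on dim probe sets (adjusted p = 0.321), and with an estimated correlation (adjusted p = 0.549).

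A group of 4 haemoglobin probe sets changed by more than any gene named here. Each is annotated to several globin genes, so it stands for no single gene and is outside the counts above. They were singled out after their values were seen. Probe set 1417714_x_at, annotated to several alpha-globin genes, went from 81.1 ± 72.8 to 944 ± 693, and 1452757_s_at, annotated likewise, from 189 ± 149 to 1818 ± 1141. Their log2 fold changes were 3.46 and 3.36 (both block adjusted p = 5.01e-06, higher in 3 of 3 pairs). A further alpha-globin set, 1428361_x_at, rose by 2.81 and a beta-globin set, 1417184_s_at, by 2.49 on the log2 scale, with block adjusted p of 2.42e-05 and 5.31e-05. Only 1417184_s_at also passed without the block, at 17.9 ± 2.51 against 180.2 ± 61.7 (adjusted p = 0.0193). That unblocked call was lost under 6 of 16 alternatives: without empty vector replicate 1 (adjusted p = 0.210), 2 (0.0642) or 3 (0.0514), without miR-9/9* replicate 1 (0.189), without a filter (0.110) and with a pseudocount of 64 (0.0576). The only other adult globin probe set above the filter, 1427219_at, stayed at 21.1 ± 8.54 against 21.8 ± 6.98. Alas2, the first enzyme of haem synthesis in red cells, and the anion exchanger Slc4a1 lay below the filter in both arms, at no more than 1.54 and 6.28 on any array. Hemgn (456 ± 133 against 533 ± 175), Epor, Tfrc and Epb42 did not pass in either fit.

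Of 11 megakaryocyte markers measured, 4 rose with the block: Itgb3, Gp9, Gp5 and Vwf. Integrin beta 3, Itgb3, went from 24.3 ± 9.61 to 131 ± 41.3, a log2 fold change of 1.85 (block adjusted p = 0.000502, against 0.0741 without it). The platelet glycoprotein genes Gp9 (135 ± 60.3 to 245 ± 102) and Gp5 (133 ± 25.6 to 177 ± 26.6) rose by 0.80 and 0.38, and von Willebrand factor, Vwf, by 0.82, all with the block. The call of Gp5 was lost without replicate 1 (adjusted p = 0.179), 2 (0.0770) or 3 (0.0943) and with quantile normalization (0.0565). Without a variance trend or without a filter those of Gp5 (adjusted p = 0.116 and 0.115) and Vwf (0.0581 and 0.0562) were lost. Without the block 0 of the markers passed, and adjusted over the list alone 4 passed with the block and 1 without it. The list ranked above other genes in both fits (median log2 fold change 0.15, camera adjusted p = 0.0106, and 0.000329 with the block), and lost the call with an estimated correlation (adjusted p = 0.750 and 0.549). Without the block it was also lost without empty vector replicate 1 (adjusted p = 0.0589) or 3 (0.126) and without miR-9/9* replicate 2 (0.175). Itga2b, the partner of Itgb3 in the platelet fibrinogen receptor, was at 1274 ± 324 against 1330 ± 315. Pf4, an abundant platelet chemokine message, was at 21.4 ± 3.10 against 21.7 ± 2.79, and neither passed.

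**Figure D1:**
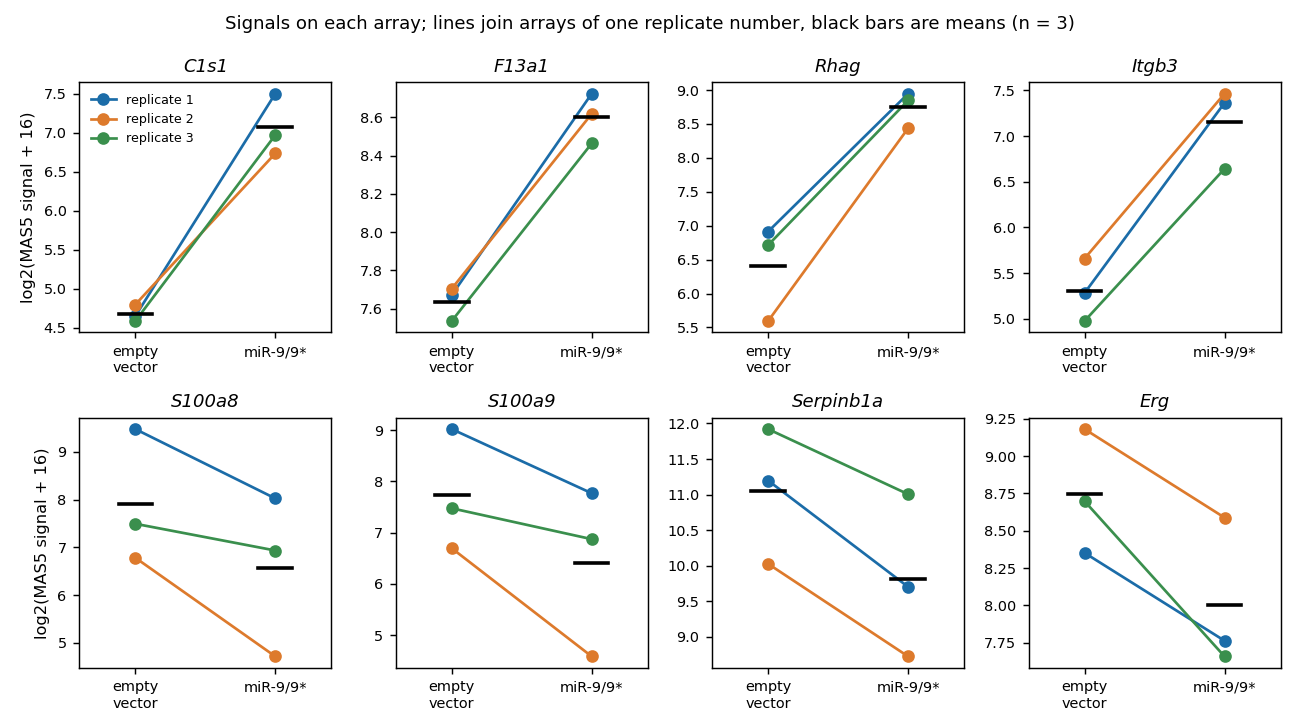
Log2(MAS5 signal + 16) of 8 genes on each of the 6 arrays, empty vector at left and miR-9/9* at right of each panel. Lines join arrays that share a replicate number, black bars are means over n = 3, and vertical scales differ between panels and do not start at 0. All 3 lines rise for C1s1, F13a1, Rhag and Itgb3 and all 3 fall for S100a8, S100a9, Serpinb1a and Erg, whose arrays overlap between the arms.

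Of 13 secondary and tertiary granule and late neutrophil genes, 4 fell with the block: S100a8, S100a9, Ltf and Stfa2l1. The alarmins S100a8 and S100a9, which form calprotectin, went from 318 ± 329 to 120.4 ± 118 and from 251 ± 221 to 104 ± 97.0, with log2 fold changes of -1.36 and -1.32 (block adjusted p = 0.0144 and 0.0155, lower in 3 of 3 pairs). Lactoferrin, Ltf, and Stfa2l1 fell by 0.95 and 0.88 on the log2 scale with the block, Stfa2l1 no longer without replicate 1 (adjusted p = 0.192). All 4 calls were lost without a filter on dim probe sets (adjusted p from 0.0993 for S100a8 to 0.153 for Stfa2l1) and without a variance trend (0.0801 for Ltf to 0.116 for S100a9). A robust fit ended those of S100a8 and S100a9 (both 0.0733), a pseudocount of 1 those of Ltf (0.0778) and S100a9 (0.0525), and a pseudocount of 64 that of Stfa2l1 (0.0634). Adjusted over the list alone 7 passed with the block, and 0 passed without it by either count. The 2 brightest members did not pass. Ngp was at 1283 ± 1073 against 970.0 ± 985 (log2 fold change -0.78, block adjusted p = 0.183, lower in 3 of 3 pairs). Lyz2 was at 444 ± 76.0 against 461 ± 28.5 (0.06, block adjusted p = 0.734), with pairs of both signs. The list ranked below other genes (median log2 fold change -0.23, camera adjusted p = 0.0452, and 0.000682 with the block). An estimated correlation ended both calls (adjusted p = 0.750 and 0.729). Without the block the call was also lost without empty vector replicate 1 (adjusted p = 0.147) or 2 (0.268) and without miR-9/9* replicate 2 (0.210) or 3 (0.177). These messages differed widely between replicate numbers in both arms, as the SDs show. Of 11 primary granule and early neutrophil genes, the elastase inhibitor Serpinb1a fell from 2407 ± 1419 to 1088 ± 849 (log2 fold change -1.24, block adjusted p = 0.000762) and Cst7 rose by 0.63. Both passed only with the block, Cst7 no longer without replicate 3 (adjusted p = 0.0627), without a filter (0.129) or without a variance trend (0.137), and 2 higher and 1 lower passed adjusted over the list alone. The list's median of -0.01 and mean of 0.01 differ in sign, and it did not pass (adjusted p = 0.917). Mpo, the myeloperoxidase gene, was at 179 ± 148 against 681 ± 825 and did not pass (block adjusted p = 0.0727), with pairs of both signs.

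Among 4 eosinophil markers measured, the granule protein gene Prg2 went from 23.4 ± 12.5 to 336 ± 404 (log2 fold change 2.38, block adjusted p = 0.0215) and Siglecf from 215 ± 74.7 to 384 ± 182 (0.73, 0.00667). Both were higher in 3 of 3 pairs and passed only with the block, and 3 passed with it adjusted over the list alone. The call of Prg2 was lost in a robust fit (adjusted p = 0.347), without a filter (0.138), without a variance trend (0.138) and with a pseudocount of 64 (0.0590), and that of Siglecf without a variance trend (0.0764). Epx, the eosinophil peroxidase gene, was at 429 ± 543 against 918 ± 1186 and did not pass (log2 fold change 0.66, block adjusted p = 0.388), with pairs of both signs. The list's median was 1.14 (camera adjusted p = 0.0125, and 0.000594 with the block). An estimated correlation ended the calls (adjusted p = 0.750 and 0.549), and without the block so did leaving out empty vector replicate 2 (adjusted p = 0.0795). Of 9 monocyte and macrophage markers only F13a1 passed, in both fits, or 1 without the block and 3 higher and 1 lower with it adjusted over the list alone. That list's median was 0.18 (camera adjusted p = 0.0824, and 0.0486 with the block). The blocked call was lost without replicate 2 (adjusted p = 0.0587), without replicate 3 (0.124), with quantile normalization (0.0571), without a filter on dim probe sets (0.151), with a pseudocount of 64 (0.0520) and with an estimated correlation (0.549).

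Of 21 measured genes reported elsewhere as miR-9 targets, 3 fell with the block: Erg, Sirt1 and Socs5. The ETS family transcription factor Erg went from 425 ± 129 to 252 ± 102, a log2 fold change of -0.74. Its block SE was 0.0971 (adjusted p = 0.00646), whereas without the block the SE was 0.277 (adjusted p = 0.996). Its second probe set lay below the filter, at 6.00 ± 4.86 against 2.95 ± 3.09. The deacetylase Sirt1, from 218 ± 12.3 to 155 ± 9.88, and the signalling inhibitor Socs5, from 159 ± 16.6 to 109 ± 21.3, fell by 0.45 and 0.49 on the log2 scale (block adjusted p = 0.0230 and 0.0233). A further probe set of Socs5 above the filter stood at -0.03, and averaging the probe sets ended its call (adjusted p = 0.183). Leaving out replicate 1 or 3 ended the calls of Sirt1 (adjusted p = 0.0962 and 0.0632) and Socs5 (0.109 and 0.0504), as did dropping the filter (0.0828 and 0.0868) or the variance trend (0.110 and 0.0905), which also ended that of Erg (0.0764). Adjusted over the list alone 5 were lower with the block, and 0 were higher by either count. Without the block 0 passed by either count. The median log2 fold change was -0.08 (camera adjusted p = 0.0486 with the block, 0.105 without it, and 0.549 with the block and an estimated correlation), and the fry test with the block did not pass (adjusted p = 0.127). The blocked call was also lost without replicate 2 (adjusted p = 0.0742) and without replicate 3 (0.0638), with a pseudocount of 64 (0.0537) and with arrays centred on their medians (0.0553). Without a filter on dim probe sets the median was 0.0012 (adjusted p = 0.276).

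Other genes named before the data were examined did not pass in either fit, with 1 exception. Rest, a repressor of neuronal genes, was at 197 ± 28.8 against 172 ± 31.1 (log2 fold change -0.19, pairs of both signs). Its only other probe set above the filter stood at -0.45, lower in 3 of 3 pairs. Actl6a was at 965 ± 177 against 873 ± 74.3, and Foxo3 at 299.6 ± 48.3 against 276 ± 53. Rest, Foxo3 and Runx1 are also on the list of reported targets. Runx1 had a log2 fold change of 0.29, Spi1 of -0.14, Il3ra of -0.39 and Myc of 0.13. Cebpa, a transcription factor of granulocyte differentiation, was at 61.6 ± 34.9 against 22.7 ± 8.72 (log2 fold change -0.91, block adjusted p = 0.0625, lower in 3 of 3 pairs). The exception was Rcor1, the CoREST scaffold, with a log2 fold change of -0.33 (block adjusted p = 0.0473). Of its 3 probe sets 2 were lower and 1 was not (0.09), and its call was lost without replicate 1 (adjusted p = 0.272) or 2 (0.0839) and when they were averaged (0.224). It was also lost without a variance trend (adjusted p = 0.187), without a filter (0.137), with quantile normalization (0.0591) and with a pseudocount of 1 (0.0523). Foxo1 (5.43 ± 0.634 against 10.2 ± 1.02), Hes1, Gfi1, Csf3r and Kit lay below the filter. Nfkb1 and Cebpe had no probe set with a single symbol and were not used here. The microRNAs themselves were not measured: the probe set for Mir9-3hg, a host transcript of the chromosomal gene, was at 13.5 ± 0.590 against 14.5 ± 11 and checks nothing about the construct.

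Genes of microRNA processing and silencing ranked above other genes. Dgcr8, the partner of Drosha, went from 127 ± 35.4 to 196 ± 43.3 and the Argonaute Ago1 from 112 ± 44.8 to 172 ± 30.9, with log2 fold changes of 0.58 and 0.60 (block adjusted p = 0.00857 and 0.0355). A further probe set of Dgcr8 above the filter stood at 0.14, and averaging its probe sets gave 0.19 and ended the call (adjusted p = 0.363). That of Ago1 was lost without replicate 3 (adjusted p = 0.0731) and without a filter (0.140). Both were lost without a variance trend (0.0648 and 0.137). Of 17 members measured these 2 passed with the block, 6 adjusted over the list alone, and 0 without it by either count. The median was 0.14 (camera adjusted p = 0.0164, and 0.00667 with the block). An estimated correlation ended both calls (adjusted p = 0.750 and 0.549), and averaging each gene's probe sets ended both as well (adjusted p = 0.104 and 0.134). Without the block the call was lost without empty vector replicate 3 (adjusted p = 0.0539) and without miR-9/9* replicate 2 (0.120).

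Genes of glycolysis and the hypoxia response ranked below other genes, with a median of -0.14 over 22 members (camera adjusted p = 0.0106, and 0.000565 with the block). An estimated correlation ended both calls (adjusted p = 0.750 without the block and 0.549 with it). Bnip3, a mitochondrial protein induced by hypoxia, fell from 372 ± 142 to 232 ± 76.7 (log2 fold change -0.62, block adjusted p = 0.00501, and 0.0648 without a variance trend). It alone passed with the block, against 4 lower adjusted over the list alone, and 0 passed without it. The glycolytic enzymes Aldoa and Pgk1 both stood at -0.07 on their brightest probe sets and did not pass. Their further probe sets, all above the filter, ran from -0.04 to -0.24 for Aldoa and stood at -0.12 and -0.33 for Pgk1. G2/M genes had a median of -0.10 over 32 members (camera adjusted p = 0.0164, and 0.00113 with the block), and these calls were lost with an estimated correlation (adjusted p = 0.978 and 0.549). Of its members 0 passed singly in limma in either fit or over the list alone, with 8 at an unadjusted p under 0.05 with the block and 0 without it. Top2a was at 2580.2 ± 299.7 against 2445 ± 586. Without the block the glycolysis call was lost without empty vector replicate 1 (adjusted p = 0.0671) and without miR-9/9* replicate 3 (0.109). The G2/M call was lost without miR-9/9* replicate 1 (adjusted p = 0.109) or 2 (0.580), and without empty vector replicate 3 its mean was 0.01.

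**Figure D2:**
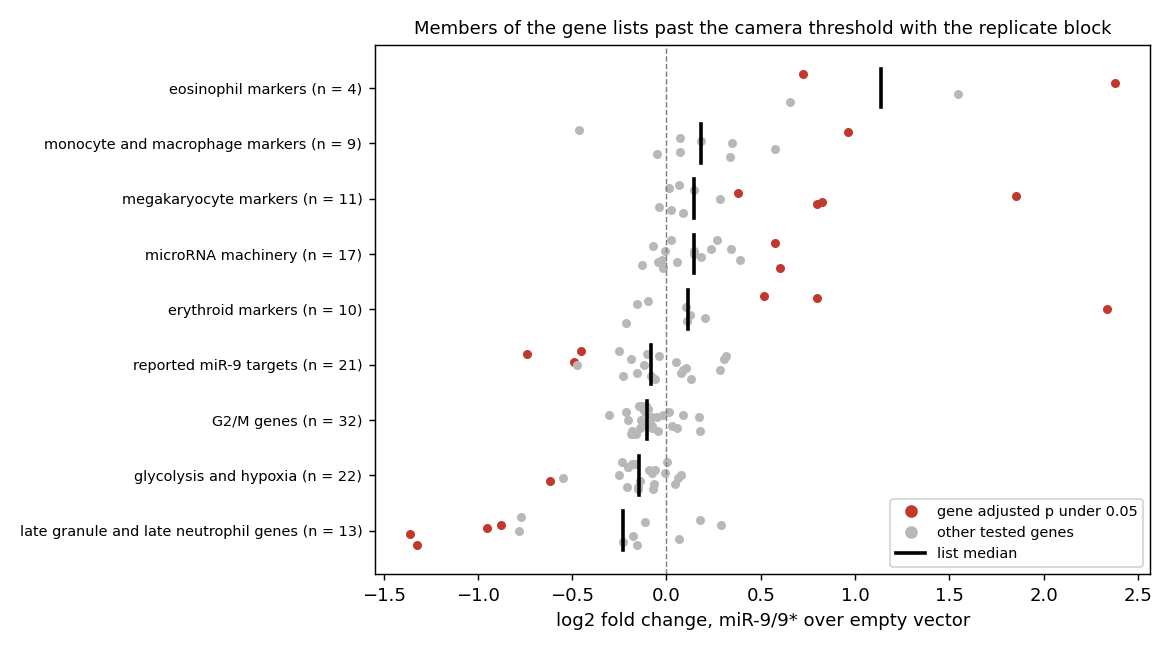
Log2 fold change of miR-9/9* over empty vector, on the log2(signal + 16) scale, for each measured member of the 9 gene lists that passed the camera threshold with the replicate block. Each dot is a gene, shifted vertically only for visibility, with genes past the threshold in red and list medians as black bars. Medians run from -0.23 for late neutrophil genes to 1.14 for the 4 eosinophil markers.

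In all, 6 of the 30 lists passed without the block and 9 with it. With an estimated correlation camera passed 0 lists in either fit, with 0 lists without the block and 1 with it at an unadjusted p under 0.05. In simulated data that alternative called 0 of 10 shifted lists with the block, so its blocked result does not separate shifted lists from others. The fry test, which asks whether a list's genes move one way on balance, passed 0 lists without the block (2 at an unadjusted p under 0.05) and with it (8 unadjusted) only microRNA machinery (adjusted p = 0.00418). Exchanging the arms within replicate number 2 gave 11 passing lists and 0 passing genes with the block. Without the block, dropping the filter on dim probe sets ended the calls of late neutrophil genes, eosinophil markers, megakaryocyte markers and microRNA machinery and left 2 lists. A pseudocount of 1 ended those of late neutrophil genes and eosinophil markers, and centring arrays on their medians those of late neutrophil and G2/M genes. The lists that did not pass included haematopoietic transcription factors (34 measured), of which Gata1, Tal1 (957 ± 10.2 to 1316 ± 186) and, outside the naming rule, Tcf4 rose with the block and Erg and Lmo2 fell, with 6 and 5 adjusted over the list alone. The calls of Tal1 (adjusted p = 0.102) and Lmo2 (0.0950) were lost without replicate 1, and that of Tal1 also without replicate 2 (0.0772). Both were lost without a variance trend (0.142 and 0.141) and without a filter (0.111 and 0.0849). Nor did the lists of the interleukin-3 response, G1/S genes, G1 cyclins, apoptosis regulators, FOXO targets and p53 targets pass. Among 27 interleukin-3 and STAT5 response genes the phosphatase Dusp6 and the receptor chain Csf2rb fell by 0.49 and 0.35 with the block, calls lost without replicate 1 (adjusted p = 0.0676 and 0.222) for Csf2rb without replicate 2 (0.162), and for both without a variance trend (0.137 and 0.141) or a filter (0.0985 and 0.121), and 5 were higher and 5 lower adjusted over the list alone. The 28 G1/S and DNA replication genes, 20 apoptosis regulators and 20 FOXO target genes had 0 passing genes in limma in either fit or over the list alone and medians of 0.02, 0.05 and 0.05. At an unadjusted p under 0.05 they held 7, 5 and 6 genes with the block and 0 without it. Of 14 G1 cyclins and CDK inhibitors 0 passed, with 1 higher and 1 lower adjusted over the list alone with the block (median 0.11). Cyclin G1, Ccng1, fell from 1926 ± 483 to 1029 ± 251 (log2 fold change -0.89, block adjusted p = 0.000502). It was the 1 of 15 p53 target genes to pass, also adjusted over the list alone in both fits, and Cdkn1a was at 1217 ± 269 against 1207 ± 349. That list's median was 0.04 and its mean -0.02.

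Of 26 adhesion and surface receptor genes, the inhibitory Fc receptor Fcgr2b (789 ± 166 to 1310 ± 282) and Cd44 rose and Itga6 and Csf2rb fell with the block, with 2 higher and 5 lower adjusted over the list alone (median -0.07). The calls of Cd44 (adjusted p = 0.176), Itga6 (0.0834) and Csf2rb (0.222) were lost without replicate 1, that of Csf2rb also without replicate 2 (0.162) and that of Cd44 without replicate 3 (0.0819). Of 22 BAF and CoREST chromatin regulators, Smarcd2 fell from 1024 ± 53.9 to 706 ± 89.5 (log2 fold change -0.53, block adjusted p = 0.00905) beside Rcor1. Both passed with the block adjusted over the list alone and 1 gene passed without it, while the list's median was 0.01 and its mean -0.0025. Angpt1 was the 1 of 5 stem and progenitor markers to pass with the block (-0.38, median 0.07), and Jund the 1 of 19 immediate early and stress genes (-0.42, median -0.01), with 2 higher and 2 lower adjusted over the list alone for the latter. Without replicate 1 the calls of Angpt1 (adjusted p = 0.143) and Jund (0.149) were lost, and without replicate 2 that of Jund (0.107). Averaging probe sets also ended those of Angpt1 (0.0906), Jund (0.601), Cd44 (0.110) and Smarcd2 (0.0565), and quantile normalization that of Jund (0.0746). Without a variance trend the calls of Fcgr2b, Cd44, Itga6, Csf2rb, Smarcd2, Angpt1 and Jund were lost, and without a filter those of the same genes except Fcgr2b. Interferon response genes (21 measured, median -0.04), NF-kB and inflammatory genes (18, 0.06), unfolded protein and ATF4 response genes (26, -0.04) and cholesterol genes (20, 0.01, with a mean of -0.01) had 0 passing genes in either fit or over the list alone. With the block 5, 3, 1 and 3 of their members had an unadjusted p under 0.05. Cytosolic ribosomal proteins (25, -0.03) and oxidative phosphorylation genes (34, -0.01) had 0 passing genes and 0 at an unadjusted p under 0.05 in either fit. Of 11 mast cell and basophil markers 0 passed, with 1 higher and 1 lower adjusted over the list alone with the block, and the median of -0.07 and mean of 0.09 differ in sign. Lymphoid markers (3 measured, median 0.08) and neuronal genes under REST (1 measured, Cplx1, 0.01) had 0 passing genes by the same counts.

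The remaining named genes were those with the largest blocked changes, and Myo1c, named for its small p without the block. Higher in 3 of 3 pairs were Ctsj, the transporters Slco1a5 and Slc39a8, Pdzk1ip1, H2-Ob, Mfsd2b, Hsd11b2 and Clu, with log2 fold changes from 2.00 for Ctsj to 1.16 for Clu. Slc39a8, which imports zinc, went from 288 ± 194 to 852 ± 670, and Mfsd2b, a lipid exporter of red cells and platelets, from 24.5 ± 10.3 to 83.4 ± 30.8. Lower in 3 of 3 pairs were Pkd2l1 (106 ± 43.6 to 22.9 ± 3.00, log2 fold change -1.58), Anxa2 (-1.04), Celf4 (-0.99), Sntb2 (-0.90) and Myo1c (-0.73). A further probe set of Anxa2 above the filter had a log2 fold change of 0.24, so its probe sets disagree, and averaging them gave -0.26 and ended the call (adjusted p = 0.212). Without a variance trend the calls of Ctsj, Slco1a5, Slc39a8, Clu, Anxa2 and Myo1c were lost, and without a filter those of Ctsj, Slco1a5, H2-Ob, Clu, Celf4 and Sntb2. Of the 53 genes named as passing with the block, 13 kept that call under all 13 processing settings and replicate numbers left out, among them Rhag, Itgb3, Gp9, Serpinb1a, Ccng1 and Mfsd2b. A further 2, C1s1 and Rap1gap, kept it wherever they had a value.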

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

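The tests of the pairing, of red cell and platelet genes and of reported targets were chosen after the results were seen. The tests by chromosome and by other splits of the arrays were fixed before. Groups of 3 arrays are too small for a test of a sample far from the others.

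Some probe sets outside the counts of genes carried a signal above that of the empty vector arrays, or below it. Of 560 tested probe sets with several symbols, 1 passed without the block and 9 were higher and 13 lower with it. The 4 haemoglobin probe sets were 1417714_x_at (log2 fold change 3.46), 1452757_s_at (3.36), 1428361_x_at (2.81) and 1417184_s_at (2.49). Beside them 1435792_at went from 7.76 to 68.5 (1.79, block adjusted p = 0.00145), 1435761_at from 39.2 to 11.5 (-1.03, 0.0137) and 1420394_s_at from 1045 to 409.5 (-1.64, 0.00243). Among probe sets with no gene symbol in the annotation used, 29 were higher and 13 lower with the block and 0 passed without it. The largest changes were 1422411_s_at (53.3 to 395, 1.78, block adjusted p = 0.0465), 1421461_at (4.86 to 36.5, 1.12, 0.0334), 1425469_a_at (145 to 65.1, -0.97, 0.00163) and 1425471_x_at (100.0 to 34.7, -1.07, 0.0371).

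With the block, 3 of 10 erythroid and 4 of 11 megakaryocyte markers were higher in miR-9/9* cells, beside 4 globin probe sets, while both lists lost their calls with an estimated correlation. In simulated data that alternative called 0 of 10 shifted lists with the block, so the loss of a blocked call does not separate shifted lists from others. Admixed mature megakaryocytes or platelets would bring Pf4, whose log2 fold change was at most 0.26 at its upper bound of 2 SE against 1.85 for Itgb3. Such a rise of Pf4 was not seen, but it rests on 1 probe set near the floor (21.4 against 21.7). Ppbp, another platelet message, lay below the filter, so this admixture is not decided. A gain or loss of a whole chromosome in one arm would shift its median. Medians were at most 0.035 on any of 20 chromosomes, which argues against it. Admixed haemoglobin-producing erythroid cells stay open: the adult globin probe sets above the filter had a median log2 fold change of 2.81, as such cells could give, whereas Epb42, a red cell message above the filter, stood at -0.15 with an upper bound of 0.077 at 2 SE, Hemgn at 0.21 and Rhd at 0.24, and Alas2, Slc4a1, Car1, Car2, Ermap, Kel, Aqp1 and Trim10 lay below the filter, where they decide nothing. An effect of the microRNAs and a drift between the transduced cultures cannot be told apart, since each arm rests on 1 construct: Gata1, Klf1, Rhag, Gp5, Gp9, Itgb3 and Vwf were all higher in 3 of 3 pairs, which both would give.

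Same-numbered arrays of the arms deviated together from their arm means, with correlations across genes of 0.491, 0.616 and 0.680. Quantile normalization left the smallest at 0.489, which argues against the array-wide distribution of signals. A labelling batch could set pair 1 apart, since the mean log2 signal of its poly-A spike-in controls was 0.955 above that of the others, against at most 0.217 between the arrays of a pair. It stays undecided for pairs 2 and 3, which had the higher correlations and whose spike-ins differed by 0.283 (means 6.50 and 6.21, against 7.31 in pair 1). States shared by cultures of one number stay open too: 21 of 28 granule and eosinophil genes (odds ratio 59.2) and 13 of 19 immediate early and stress genes (odds ratio 42.1) were among the 511 genes varying most between pairs, but these lists were picked after that ranking was seen, so the ratios restate it and decide nothing.

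The reported miR-9 targets had a median log2 fold change of -0.08, at percentile 1.20 of 10000 random lists matched for expression. An effect of the microRNA on the group would give this, and so could indirect changes in the cells, since seed matches were not examined. Chance is not excluded either, because the random lists drew genes one by one and ignored correlation between members. With an estimated correlation camera gave an unadjusted p of 0.246 without the block and 0.116 with it. Whether Erg alone sets the shift stays open: without it the percentile was 2.36, but 1 member can hardly move a median, and the unadjusted camera p with the block went from 0.0146 to 0.0563. The adjusted p with the block ran from 0.0165 to 0.549 over the alternatives.

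Other splits of the 6 arrays are too few for a share under 0.05. Without the block the real split gave 6 genes and the highest of the other 9 splits 1. For lists the real split gave 6 and the 3 other splits that part every pair gave 4, 3 and 1. The 6 splits that part only 1 pair, and so set the replicate numbers against each other, gave 4 to 9 lists, and 6 of the 10 splits gave at least 6. With the block, which removes the replicate numbers, the real arms gave 302 genes and the highest of the 3 other exchanges within pairs 0. For lists the real arms gave 9 and the exchange of pair 2 gave 11, so 2 of the 4 gave as many.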

How the results depend on the processing

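The alternatives that combine the block with another setting were chosen after the data were seen, and all others before. Without the block, the genes higher in miR-9/9* cells and the genes lower in miR-9/9* cells numbered 2 and 4. The replicate block gave 154 and 148, array weights 14 and 12, a pseudocount of 1 gave 1 and 1, and eBayes without trend 1 and 2. Quantile normalization and centring on the median each gave 3 and 2. With all probe sets as units limma passed 2 higher and 0 lower (806 probe sets with an unadjusted p under 0.05). With no filter on dim probe sets and with a stricter filter that keeps the brighter probe sets it passed 0 and 0, at 892 and 373 genes with an unadjusted p under 0.05. An adjusted p under 0.01 left 0 and 0 of the 470 genes with an unadjusted p under 0.05, and a change of at least 2-fold 1 higher. Leaving out 1 array gave 0 to 3 higher and 0 to 4 lower: 0 and 0 without empty vector replicate 1, 2 and 0 without empty vector replicate 2, 1 and 1 without empty vector replicate 3, and 1 and 0 without miR-9/9* replicate 1 or 2. A stricter threshold passes fewer genes by construction, and for the other settings the cause was not tested.

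With the block, an adjusted p under 0.01 left 50 and 41 genes and a change of at least 2-fold 17 and 9. No filter on dim probe sets gave 40 and 34, eBayes without trend 21 and 17, averaged probe sets 100 and 87, and centring on the median 166 and 225. Leaving out a replicate number, with 1 residual degree of freedom, gave 86 to 188 higher and 76 to 194 lower, with 86 and 76 without replicate 1. The cause was not tested.

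The gene lists past the threshold numbered 6 without the block. They were 2 with no filter, 10 with the stricter filter, 2 to 9 with 1 array left out (2 without miR-9/9* replicate 2, 9 without miR-9/9* replicate 1) and 0 with an estimated correlation or with fry (0 and 2 lists unadjusted). With the block 9 lists passed, 7 to 9 with a replicate number left out, 0 with an estimated correlation (1 unadjusted) and 1 with fry (8 unadjusted). In data simulated with noise independent between genes, the estimated correlation with the block found 0 of 10 shifted lists. Camera used a variance trend under every setting. The settings of the variance model and array weights were not passed on to the set tests, so those settings do not test these calls.

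The median shift of reported miR-9 targets was -0.081. It passed with the block (-0.081), in the brighter probe sets (-0.11) and with averaged probe sets (-0.053), and was 0.0012 with no filter in both fits. Leaving out 1 array gave -0.11 to -0.034, and it passed without empty vector replicate 3 (-0.11) and without miR-9/9* replicate 1 (-0.10). With the block it no longer passed with a pseudocount of 64 (-0.073), centred arrays (-0.10), an estimated correlation or fry (both -0.081). Leaving out a number gave -0.11 to -0.067, and the call was lost without replicate 2 (-0.071) and without replicate 3 (-0.11). The cause was not tested.

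Means that changed sign follow where the list passed in the main setting or in the alternative. Changes of sign between means that passed in neither are not listed. With the stricter filter the mean log2 fold change of mast cell and basophil markers was -0.18 in both fits, and the list, which did not pass in the main setting, passed there. Without empty vector replicate 3 the mean log2 fold change of G2/M genes was 0.011 (-0.17 to 0.011 over single arrays left out), the mean log2 fold change of immediate early and stress genes 0.43 (-0.60 to 0.43), the mean log2 fold change of cytosolic ribosomal proteins 0.062 (-0.077 to 0.062) and the mean log2 fold change of oxidative phosphorylation 0.10 (-0.10 to 0.10). Without miR-9/9* replicate 1 the mean log2 fold change of primary granule and early neutrophil genes was -0.36 (-0.36 to 0.36). With the block and without replicate 3 the mean log2 fold change of cytosolic ribosomal proteins, replicate block, was 0.050 (-0.090 to 0.050). The cause was not tested.

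Of 1871 values for 111 named genes without the block, 1758 kept their side of the threshold, and 49 lost and 64 gained a call. Among the 1758, 90 values changed sign without passing in either setting, and 0 called values changed sign. Of 679 values for 53 genes called with the block, 572 kept their call and 107 lost it. Of the values for 28 lists, 476 of 530 were counted as unchanged without the block and 391 of 418 with it. A change of sign was counted only where the list passed in the main setting or in the alternative. The settings of the variance model and array weights left the list tests as they were, so their values could not lose a call. Alternatives on seed matches in 3' untranslated regions, fixed before, were not run. Signals near 16 or below are compressed by the pseudocount and lie near background, so changes of dim genes such as Foxo1 and Hes1 are not resolved.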

Other observations

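The test of actin genes was chosen after its result was seen. Among genes of the actin cytoskeleton, 11 of 46 measured were lower with the block and 0 higher, against 148 lower among all 10208 genes. The list was written after genes past the threshold had been read, so the count says nothing on whether the group moved. Without the block 0 of the 11 passed in limma. Gelsolin, Gsn, which severs actin filaments, went from 1440 ± 304 to 833 ± 111 (log2 fold change -0.77, block adjusted p = 0.00239), and the non-muscle myosin Myh9 from 2846 ± 412 to 1864 ± 126 (-0.60, 0.00653). The bundling protein Lcp1 went from 1782 ± 99.3 to 1289 ± 48.1 (-0.46, 0.00905). The focal adhesion genes Vcl and Zyx fell by 0.45 and 0.46 and the adaptor Pdlim5 by 0.64 on the log2 scale. The actins Actb and Actg1 and the depolymerising factor Cfl1 did not pass, with log2 fold changes of -0.00, -0.05 and -0.04. A coordinated fall of actin cytoskeleton genes may be worth a test on other samples, since the 11 genes cannot decide it here.

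Some genes differed widely between replicate numbers in both arms. The immediate early gene Fos had pair means of 6.06, 5.87 and 10.6 in log2(signal + 16), and Socs3, a feedback inhibitor of cytokine signalling, 7.95, 7.75 and 12.2. The eosinophil peroxidase gene Epx had pair means of 10.6, 6.52 and 7.98. Across the 10208 genes, 9.82% had arms that did not overlap, against 10% by chance for 3 against 3. Changes had the same sign in all 3 pairs for 39.0%, against 25% by chance for independent pairs. Genes are not independent, so with 3 pairs either share can lie far from its chance value, and neither difference was tested.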
